A study of Homo sapiens with 12 samples.

How the data were processed

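RNA was sequenced from 2 human non-small-cell lung cancer cell lines, H1299 and H1703, each given the histone deacetylase inhibitor SAHA (vorinostat, a hydroxamate that blocks zinc-dependent deacetylases) or its DMSO vehicle. The 12 libraries fall into 4 groups of 3: H1299 with DMSO, H1299 with SAHA, H1703 with DMSO and H1703 with SAHA. Group and replicate number came from the sample titles. The treatment protocol in the labels lists SAHA at 0, 2.5, 10 or 40 µM for 24 h, with 0.1% DMSO as vehicle. It does not say which dose the sequenced samples received, nor whether both lines received the same one, so no result below belongs to a stated dose. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

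Per the labels, polyadenylated RNA was converted to paired-end libraries and sequenced on one NovaSeq instrument type. The labels contradict themselves on strand: one passage names a directional kit, another an un-stranded library. Whether the counting used strand is not given in the sources used here. Values of antisense genes and of genes that overlap another gene are therefore uncertain, as are those of near-identical copies. The series text states a median of 55M reads per sample, whereas the totals of the count columns run from 14.4M to 19.4M; what separates them is not given in the sources used here.

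The authors deposited 1 table per line, each with 58302 Ensembl genes, their symbols and their positions. Per the file headers, each library has a column of raw counts and a column of FPKM values. The count columns hold whole numbers that are not normalized. The deposited FPKM values equal the count divided by the column total and by one length per gene, checked to within 1% in 100.0% of 180885 values; they were used for that check alone. The submitters' processing notes name FastQC 0.11.9, fastp, HISAT2 2.1.0, StringTie 1.3.3b and edgeR 3.30.3 and the genome build GRCh38, without the role of each, so the counting tool and the annotation release are not given in the sources used here. Of the genes, 20242 had no count in any library and 19817 were protein-coding in the table's own annotation. Every gene had the same position in both tables. Control columns carry a shorthand in place of the treatment name and were assigned to DMSO because each line has only these 2 groups of 3. No pair of replicate libraries agreed within sampling noise: chi-square per degree of freedom ran from 10.9 to 24.7 over the pairs of one group.

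Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment over all genes tested, with a gene called at an adjusted p below 0.05. A second count took the called genes that also changed 2-fold or more. Each line was fitted alone (SAHA against DMSO, 3 against 3). The difference of the SAHA effect between lines was tested as an interaction, H1703 minus H1299, in 1 fit over all 12 libraries, and the same fit gave the difference between the lines under DMSO. Standard errors of log2 fold changes were taken as the fold change divided by the root of the F statistic. Levels are counts-per-million (CPM) with the TMM scaling over all 12 libraries, as mean ± SD of 3 libraries. Calls in both lines were counted by direction against the number that independent lists of the same sizes would share. The lines have separate controls.

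Gene lists, 42 in number and 21 of them core lists for naming genes, were fixed before the data were examined, together with the designs, the alternatives and the rule for named genes. All 848 list entries matched a symbol of the tables. A list with 4 or more tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over lists within a comparison. Camera asks whether a list's genes rank apart from the other genes. It was repeated with the correlation estimated from the residuals. fry was run beside it: its PValue asks whether a list's genes move on balance one way, its PValue.Mixed whether they change in either direction, and neither compares the list with other genes.

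Named genes followed a rule. Per SAHA comparison it took the 6 called genes with the largest fold change in each direction, among those with a mean log2 CPM of 3 or more and every SAHA library on one side of every DMSO library. To these were added, for each core list, the 2 members with the smallest adjusted p and a mean log2 CPM of 1 or more plus one of the opposite direction, and a set of fixed genes. For the interaction it took the 6 most positive and 6 most negative called values among genes with a mean log2 CPM of 3 or more, and for the difference under DMSO the lung adenocarcinoma and squamous marker lists and the fixed genes. A few genes that the rule takes are not reported here, though counts over lists and over named genes include them. Symbols are those of the tables, such as H1F0 for the linker histone H1.0. Where all libraries of a group had 0 counts, a fold is given as a bound against a floor of 3 counts per library. Where a group held 1 to 3 counts in all, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

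The test was tried on simulated counts for the real genes, with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold. In the H1299 design (15749 genes) it recovered 28.4% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 15 false calls among 180. In the H1703 design (15839 genes) the shares were 35.8%, 77.6% and 98.5%, with 21 false calls among 193. In the interaction design (17514 genes) they were 4.48%, 38.8% and 69.7%, with 5 false among 80. Genes that changed little, and above all small differences between the lines, were therefore often missed in the simulation. It changed far fewer genes than were called in the data, which makes the adjusted threshold stricter. These shares are therefore not those of the real comparisons. With the mitosis list lowered in the simulation, camera called that list alone in each line. With no list changed, it called 1 of 39 lists in the interaction.

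The labels carry a batch tag, Repeat1 to Repeat3, which gives each replicate number to 1 sample of every group. What the tag marks is not given in the sources used here. The samples were treated as paired by it in alternatives, not in the main fit. Deviations from the group means correlated between same-numbered DMSO and SAHA libraries at r from -0.033 to 0.054, against -0.059 to 0.061 between libraries of different number. The fit without the pairing was the main one, and a fit with the replicate number as a block was run for the genes of each comparison, the overlap, and the lists of both SAHA effects and of the interaction. The other alternatives were DESeq2 1.42.0, its size factors in edgeR, library size alone, no filter, a stricter filter, one fit over 12 libraries, DMSO libraries alone, and leaving out each library in turn. Chosen after seeing the data were fits without mitochondrially encoded genes, with protein-coding genes alone, and with genes expressed in both lines. Tests outside these fits used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures used matplotlib 3.10.9. No test of histology was made.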

Results

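Messenger RNA was measured in 12 libraries of the lung cancer lines H1299 and H1703 after 24 h with the histone deacetylase inhibitor SAHA or with its DMSO vehicle, 3 libraries per group. Both are established lines of human non-small-cell lung cancer. The title of the series places the work in lung adenocarcinoma and lung squamous carcinoma, but the labels used here do not tie either line to a histology. Total counts were 15.8M ± 0.513M in H1299 with DMSO (mean ± SD, n = 3) and 15.1M ± 0.819M with SAHA, and 16.7M ± 1.55M and 17.8M ± 1.44M in H1703. At similar depth, more genes were counted after SAHA: genes with 10 or more counts numbered 16033 ± 174 in H1299 with DMSO and 17534 ± 94.7 with SAHA, and 16146 ± 179 and 17348 ± 197 in H1703. Mitochondrially encoded genes took 2.12 ± 0.138% of the counts in H1299 with DMSO and 4.10 ± 0.121% with SAHA, against 5.88 ± 0.418% and 9.57 ± 1.19% in H1703. Gene changes below are log2 fold changes ± SE from edgeR's quasi-likelihood test with 3 libraries per group, and "adjusted p" is Benjamini-Hochberg over all genes of a comparison, or over all lists for camera. Member counts of a list are over all genes tested; those adjusted over the list alone were the same except where they are given.

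**Figure D1:**
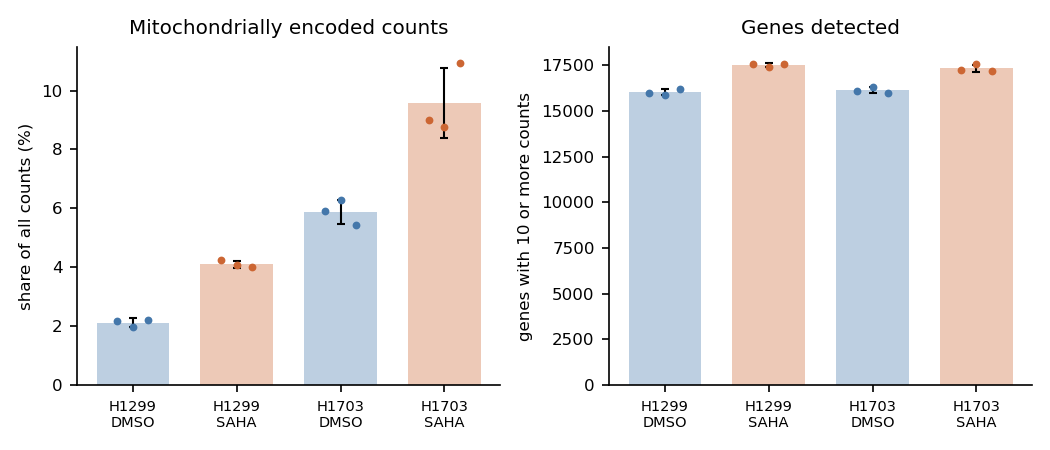
Share of counts from mitochondrially encoded genes (left, percent of the library total) and number of genes with 10 or more counts (right) in each of the 12 libraries; points are libraries, bars are means of 3 and whiskers are SD. In both lines the SAHA libraries lie above the DMSO libraries on both measures, with mean mitochondrial shares of 2.12% and 4.10% in H1299 and 5.88% and 9.57% in H1703.

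The first question was what SAHA does to the H1299 transcriptome. The cell division programme fell: all 32 mitosis genes tested were lower, among them KIF20A (-2.31 ± 0.09), a kinesin of cytokinesis, and CCNB2 (-2.30 ± 0.09), a mitotic cyclin. CDKN1A, which encodes the CDK inhibitor p21, rose 4.17-fold, from 83.5 ± 7.8 to 362 ± 24 CPM (log2 2.06 ± 0.10, edgeR adjusted p = 3.8e-07). Neuronal genes rose: 33 of 37 tested members were higher, with the axonal adhesion gene L1CAM at 7.91 ± 0.20 and the secreted neuropeptide precursor VGF at 4.50 ± 0.14. MHC class II genes, normally restricted to antigen-presenting cells, rose in 7 of 8 tested members, though some, such as HLA-DRA, stayed at low counts. The transcription factor gene FOSL1, an AP-1 subunit, fell 11.6-fold, from 409 ± 11 to 36.6 ± 4.9 CPM (-3.54 ± 0.11, edgeR adjusted p = 8.2e-08).

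Within the cell cycle lists of H1299, the mitosis list had a median log2 fold change of -1.79 (camera adjusted p = 5.7e-13, adjusted p = 0.297 with an estimated correlation). Of 34 DNA replication genes, 32 fell and 2 did not pass (median -1.10, camera adjusted p = 8.6e-11, adjusted p = 0.344 with an estimated correlation). An example is RRM1 (-1.39 ± 0.07), a ribonucleotide reductase subunit. Of 22 homologous recombination and Fanconi anaemia genes, 18 fell and 1 rose (median -1.19, camera adjusted p = 5.6e-06, adjusted p = 0.160 with an estimated correlation). The central Fanconi pair FANCD2 (-1.89 ± 0.10) and FANCI (-1.58 ± 0.09) fell, and the member that rose was FANCF (1.24 ± 0.18), an adaptor of the Fanconi core complex. Ribosome biogenesis genes fell in 17 of 26 with none higher (median -0.48, camera adjusted p = 0.00086, adjusted p = 0.443 with an estimated correlation). Among 16 G1/S cyclins and kinases, 11 fell and 4 rose (median -0.75, camera adjusted p = 0.0795). CCNA2, cyclin A2, fell (-1.72 ± 0.09), while CCND2, cyclin D2, rose from 0.624 ± 0.10 to 23.9 ± 2.8 CPM (5.18 ± 0.19). CCND1, cyclin D1, rose slightly (0.29 ± 0.08). Of 7 CDK inhibitors 4 rose and 2 fell (median 0.51, camera adjusted p = 0.531), with CDKN2B up (1.88 ± 0.10) and CDKN2C down (-1.04 ± 0.08). The 22 p53 targets went both ways, 10 up and 7 down (median 0.45, camera adjusted p = 0.320).

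Among chromatin genes of H1299, 14 of 17 writers and silencers fell and none rose (median -0.83, camera adjusted p = 0.00011, adjusted p = 0.160 with an estimated correlation). They include DNMT1 (-1.70 ± 0.09), the maintenance DNA methyltransferase, and its partner UHRF1 (-1.73 ± 0.13). The 11 histone deacetylases divided: HDAC5 (1.60 ± 0.10) and HDAC11 (1.55 ± 0.14) rose and HDAC7 (-0.60 ± 0.11) fell, with 3 up, 2 down and 6 not passing (median 0.09, camera adjusted p = 0.902). The class I genes HDAC1 (-0.18 ± 0.08, edgeR adjusted p = 0.057) and HDAC2 (-0.16 ± 0.08) did not pass. HDAC3 did not either (0.41 ± 0.16, edgeR adjusted p = 0.052), but passed with the replicate number as a block (0.0122; over all alternatives 0.0122 to 0.148). Nor did HDAC6 (0.09 ± 0.11). Of 7 sirtuins 3 rose and 1 fell (median 0.19, camera adjusted p = 0.422). In the list of linker and replication-independent histones, 3 of 10 rose and 3 fell (3 and 5 adjusted over the list alone; median -0.28, camera adjusted p = 0.523). H1F0, the linker histone of non-dividing cells, rose 2.41-fold (1.27 ± 0.08), and H2AFZ, the variant H2A.Z, fell (-1.42 ± 0.09). Clustered histone genes, whose transcripts are near-identical copies and mostly lack poly(A) tails, rose in 11 of 16 and fell in 3 (median 1.18, camera adjusted p = 0.061).

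Among lineage genes of H1299, the neuronal list had a median of 3.24, or 2.79 with genes absent from DMSO set at their bound (camera adjusted p = 8.0e-10, adjusted p = 0.160 with an estimated correlation). Of its members, 2 fell, among them the neurofilament gene NEFH (-0.63 ± 0.10). Of 20 epithelial junction and keratin genes 10 rose and 2 fell (median 0.94, camera adjusted p = 0.0577). The tight junction gene TJP3 rose (5.71 ± 0.15), as did plakoglobin, JUP (2.66 ± 0.14), while the desmosomal PKP3 fell (-0.75 ± 0.15). Of 20 mesenchymal genes 11 rose and 7 fell (11 and 8 adjusted over the list alone; median 0.93, camera adjusted p = 0.349). The matrix protein gene TGFBI (1.98 ± 0.10) rose, and the matrix metalloprotease MMP14 (-1.50 ± 0.10) and vimentin, VIM (-0.84 ± 0.12), fell. CDH1, E-cadherin, was too low to be tested in H1299. Only 6 of 20 lung adenocarcinoma markers could be tested, 3 up and 1 down (median 0.48, camera adjusted p = 0.643). LAMP3 (1.27 ± 0.13) and NKX2-1 (1.07 ± 0.23, at 1.26 ± 0.19 and 2.74 ± 0.062 CPM) rose and ABCA3 fell (-0.44 ± 0.12). Of 27 squamous markers 6 were tested, 3 up and 2 down (median 0.10, camera adjusted p = 0.755). The Notch ligand gene JAG1 rose (1.64 ± 0.11), S100A2 fell (-1.60 ± 0.21) and SOX2 did not pass (-0.28 ± 0.20). Receptor tyrosine kinases rose in 14 of 25 and fell in 5 (median 0.60, camera adjusted p = 0.123). FGFR4 rose (2.02 ± 0.11) and AXL fell from 1356 ± 36.8 to 305 ± 30.0 CPM (-2.21 ± 0.10). PDGFRA rose from 0.078 ± 0.091 to 1.401 ± 0.33 CPM, and neither EGFR (-0.26 ± 0.13) nor FGFR1 (0.17 ± 0.20) passed. Of 15 cancer-testis antigens 9 rose and none fell (median 0.28, camera adjusted p = 0.045, adjusted p = 0.636 with an estimated correlation). Tubulins and cytoskeletal genes went both ways, 9 up and 6 down of 17 (9 and 7 adjusted over the list alone; median 0.72, camera adjusted p = 0.422). So did drug transporters, 6 up and 2 down of 10 (median 0.60, camera adjusted p = 0.340).

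Immune genes of H1299 divided by class. The MHC class II list had a median of 4.41, or 3.45 with absent genes at their bound (camera adjusted p = 0.00067, adjusted p = 0.160 with an estimated correlation). Some levels were low: HLA-DRA had 0 counts in each DMSO library and 16, 19 and 15 with SAHA. HLA-DRB1 had 0, 2 and 3, then 21, 19 and 16. The class II genes CD74 (4, 4 and 0, then 2, 0 and 0) and CIITA (9, 6 and 12, then 12, 7 and 13) showed no such rise. Immune checkpoint and NK ligand genes rose in 9 of 13 and fell in none (median 1.08, camera adjusted p = 0.025, adjusted p = 0.344 with an estimated correlation). CD274, which encodes PD-L1, rose from 2.33 ± 0.53 to 9.04 ± 0.90 CPM (1.90 ± 0.20). MHC class I presentation genes did not move together, 7 up and 9 down of 18 (median -0.49, camera adjusted p = 0.422). HLA-F rose (2.76 ± 0.15) and ERAP1, a peptide-trimming protease, fell (-1.23 ± 0.08). Of 27 interferon-stimulated genes 14 fell and 8 rose (median -0.62, camera adjusted p = 0.210), with IFIT2 down (-2.54 ± 0.18) and tetherin, BST2, up (5.00 ± 0.34). Of 15 NF-kB targets and cytokines 5 rose and 4 fell (median 0.16, camera adjusted p = 0.902), with NFKB2 up (0.75 ± 0.08) and NFKB1 (-1.63 ± 0.11) and LIF (-1.76 ± 0.14) down. Beside these changes, markers of other cell types were few. Of 11 lymphoid markers 0 reached the test. Of 11 myeloid markers 5 did, 3 up and 2 down (median 5.18, or 2.78 at the bound, camera adjusted p = 0.340). Of the others tested, 2 of 3 endothelial, 2 of 2 fibroblast and 5 of 6 ciliated-cell markers rose, the last with a median of 1.66 (camera adjusted p = 0.0691).

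Among genes of metabolism and stress in H1299, all 13 mitochondrially encoded mRNAs rose together with the mitochondrial share of the libraries (median 0.77, camera adjusted p = 0.00023, adjusted p = 0.561 with an estimated correlation). Nuclear genes of oxidative phosphorylation did not, with 5 up and 11 down of 31 (median -0.04, camera adjusted p = 0.531). Lysosome and autophagy genes rose in 14 of 26 and fell in 2 (median 0.42, camera adjusted p = 0.045, adjusted p = 0.636 with an estimated correlation). Metallothioneins and antioxidant genes rose in 13 of 18 and fell in 2 (13 and 3 adjusted over the list alone; median 0.85, camera adjusted p = 0.0061, adjusted p = 0.344 with an estimated correlation). The metal-binding MT1X rose (2.63 ± 0.10), sulfiredoxin, SRXN1, rose (2.09 ± 0.07) and superoxide dismutase 1, SOD1, fell (-0.57 ± 0.14). Apoptosis genes went both ways. Of 22 pro-apoptotic genes 7 rose and 9 fell (median 0.12, mean 0.28, camera pointing down at adjusted p = 0.902). The death receptor gene TNFRSF10B rose (1.03 ± 0.09) and BID fell (-1.30 ± 0.10). Of 9 anti-apoptotic genes 3 rose and 1 fell (median 0.08, mean -0.12, camera pointing up at adjusted p = 0.925). BCL2 (0.67 ± 0.13), BCL2L1 (0.35 ± 0.07) and MCL1 (0.33 ± 0.07) rose and CFLAR fell (-0.92 ± 0.12). Cholesterol biosynthesis had 6 up and 4 down of 22 (5 and 3 adjusted over the list alone; median 0.03, camera adjusted p = 0.902). HMGCS1 (0.83 ± 0.08) and TM7SF2 (1.31 ± 0.13) rose. Glycolysis had 5 up and 8 down of 20 (median -0.16, camera adjusted p = 0.422), and the ER stress response 10 up and 4 down of 18 (median 0.44, camera adjusted p = 0.271). Heat shock and HSP90 genes had 5 up and 8 down of 15 (median -0.30, camera adjusted p = 0.340). Ribosomal proteins had 7 up and 4 down of 30 (6 and 4 adjusted over the list alone; median 0.04, camera adjusted p = 0.902).

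The largest rises in H1299 began at or near 0 counts. STMN2 (ENSG00000104435, GRCh38 chromosome 8, 79610814 to 79666175), a microtubule regulator of growing axons, had 0 counts in each DMSO library and 250, 234 and 289 counts with SAHA, at least 88.4-fold higher. KIF1A (ENSG00000130294, chromosome 2, 240713764 to 240820308), a kinesin of synaptic vesicle transport, rose 303-fold, from 0.253 ± 0.063 to 82.3 ± 7.5 CPM (8.24 ± 0.18, edgeR adjusted p = 1.4e-08). With 1 to 3 DMSO counts in all, AL078612.2 was 1853 times as high (counting interval 332 to 73230), XKR7 969 times (268 to 8010), HPCAL4, a neuronal calcium sensor, 682 times (233 to 3310) and AC036222.1 415 times (142 to 2014). Downwards, the mitotic spindle gene ASPM (-3.24 ± 0.24) and the iron regulator HFE (-3.27 ± 0.25) fell beside FOSL1 (ENSG00000175592, chromosome 11, 65892049 to 65900573). Another 3 of the 6 largest falls belong to genes that overlap other genes. BLOC1S5-TXNDC5, a read-through gene over TXNDC5, had 4099, 4497 and 4306 counts with DMSO and 0 with SAHA, at least 1388-fold lower. Its call was lost in one fit over 12 libraries (adjusted p = 0.0574; over all alternatives 4.8e-33 to 0.0574), and in H1703 with DMSO its counts were 0, 1733 and 0. ZC3H11A fell (-3.48 ± 0.23), and AC007240.1 (-3.78 ± 1.21, edgeR adjusted p = 0.045) lost its call with the replicate number as a block (0.140; over all alternatives 0.00099 to 0.140).

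In all, edgeR called 11016 of 17277 genes in H1299, 5757 higher and 5259 lower with SAHA. Of these, 5251 changed 2-fold or more, 3338 up and 1913 down. Camera called 12 of 39 lists, 7 up and 5 down, 0 of them with an estimated correlation, where the lowest adjusted p was 0.160 and 5 lists had an unadjusted p below 0.05; fry's PValue was below 0.05 for 32 lists. The calls of the lysosome list (adjusted p = 0.0526) and the cancer-testis list (0.0574) ended with the replicate number as a block, and both also when libraries of replicate 3 were left out (0.246 and 0.173). Over all alternatives their adjusted p ran from 0.0125 to 0.636 and from 0.0149 to 0.636. CCND1 lost its call without DMSO replicate 1 (0.0589; over all alternatives 0.00038 to 0.0589). MYC, not called (-1.67 ± 1.17, adjusted p = 0.274), turned to 0.50 (adjusted p = 0.0334; over all alternatives 0.0334 to 0.665) without DMSO replicate 3, whose count of 1367 stood against 120 and 102.

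The same question was asked of H1703. Division genes fell here too: all 32 mitosis genes were lower, with a median of -3.52. TOP2A, the topoisomerase of dividing cells, went from 660 ± 26 to 49.2 ± 2.2 CPM (-3.73 ± 0.08), and KIF11, the spindle kinesin Eg5, fell too (-3.43 ± 0.09). CDKN1A rose 3.32-fold, from 222 ± 7.5 to 728 ± 30 CPM (1.73 ± 0.07, edgeR adjusted p = 5.8e-08). Neuronal genes rose in 32 of 36, with VGF at 6.98 ± 0.10 and synaptophysin, SYP, at 4.49 ± 0.09. All 11 tested MHC class II genes rose. TXNIP, a thioredoxin-binding protein, rose 75.7-fold (6.24 ± 0.34), from 4.18 ± 2.0 to 316 ± 16 CPM, and SOX2, a transcription factor of squamous and stem cells, fell from 40.0 ± 2.2 to 5.26 ± 1.1 CPM (-2.91 ± 0.15).

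In the cell cycle lists of H1703, mitosis had a camera adjusted p of 2.4e-15 (adjusted p = 0.0939 with an estimated correlation). All 34 DNA replication genes fell (median -2.17, camera adjusted p = 4.0e-14, adjusted p = 0.0939 with an estimated correlation), including the helicase subunits MCM5 (-3.24 ± 0.09) and MCM4 (-2.85 ± 0.09). Homologous recombination and Fanconi genes fell in 20 of 22 and rose in 2 (median -2.33, camera adjusted p = 1.6e-07, adjusted p = 0.0681 with an estimated correlation). BRCA1 (-3.36 ± 0.11) and FANCD2 (-3.33 ± 0.11) fell and FANCE, of the core complex, rose (0.81 ± 0.13). Of 16 G1/S genes 12 fell and 2 rose (2 up and 13 down adjusted over the list alone; median -0.96, camera adjusted p = 0.0024, adjusted p = 0.162 with an estimated correlation). CCNA2 (-4.49 ± 0.11), the S-phase activator E2F1 (-2.53 ± 0.10) and CCND1 (-0.75 ± 0.07) fell. CCND2 was 289 times as high with SAHA (counting interval 51.5 to 11473), at 6.16 ± 1.8 CPM. Ribosome biogenesis genes fell in 20 of 26 and 1 rose (median -0.59, camera adjusted p = 0.00012, adjusted p = 0.162 with an estimated correlation). Of 5 tested CDK inhibitors 3 rose and 2 fell (median 0.31, camera adjusted p = 0.730), with CDKN2D up (1.57 ± 0.13) and CDKN1C down (-1.43 ± 0.22). The 24 p53 targets divided into 9 up and 10 down (median -0.08, mean 0.10, camera pointing down at adjusted p = 0.915).

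Chromatin writers and silencers of H1703 fell in 14 of 17 with none higher (median -1.27, camera adjusted p = 0.00012, adjusted p = 0.121 with an estimated correlation), with UHRF1 at -2.68 ± 0.12 and DNMT1 at -1.67 ± 0.08. Of 11 histone deacetylases 4 rose and 2 fell (median -0.01, mean 0.31, camera pointing up at adjusted p = 0.834). HDAC5 (2.14 ± 0.08) and HDAC3 (1.55 ± 0.23) rose, and HDAC7 (-1.52 ± 0.12) and HDAC6 (-0.47 ± 0.10) fell. HDAC1 (-0.04 ± 0.07) and HDAC2 (-0.01 ± 0.07) did not pass. Of 7 sirtuins 4 rose and 2 fell (4 and 3 adjusted over the list alone; median 0.46, camera adjusted p = 0.760). Linker and replication-independent histones had 2 up and 3 down of 10 (median 0.01, mean -0.44, camera pointing down at adjusted p = 0.808). H1F0 rose (1.17 ± 0.08), and H2AFY2 (-4.40 ± 0.13) and H2AFX (-1.59 ± 0.09), the variants macroH2A2 and H2A.X, fell. Clustered histones rose in 11 of 15 and fell in none (median 1.25, camera adjusted p = 0.0043, adjusted p = 0.162 with an estimated correlation).

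For lineage genes of H1703, the neuronal list had a median of 3.18 (camera adjusted p = 1.0e-09, adjusted p = 0.0654 with an estimated correlation); its falling member was CPLX2, a complexin of synaptic release (-3.11 ± 0.08). Epithelial genes went both ways, 10 up and 7 down of 22 (10 and 8 adjusted over the list alone; median 0.04, camera adjusted p = 0.857). Keratin 19, KRT19, rose from 15.9 ± 1.9 to 309 ± 32 CPM (4.29 ± 0.12). CDH1 (-1.51 ± 0.14, from 92.4 ± 17 to 32.1 ± 2.4 CPM) and PKP3 (-2.99 ± 0.12) fell. Mesenchymal genes had 7 up and 8 down of 23 (median 0.03, camera adjusted p = 0.954). Fibronectin, FN1, rose (1.48 ± 0.07), the actin-binding TAGLN fell (-2.06 ± 0.18) and VIM did not pass (-0.04 ± 0.06). Of 7 adenocarcinoma markers tested 4 fell and 2 rose (median -1.23, camera adjusted p = 0.499), with LAMP3 up (4.57 ± 0.21). Of 11 squamous markers 7 rose and 2 fell (median 1.14, camera adjusted p = 0.143), with the p63 target PERP up (1.14 ± 0.07) beside the fall of SOX2; TP63 did not pass (0.31 ± 0.23). Receptor tyrosine kinases had 16 up and 7 down of 26 (median 0.65, camera adjusted p = 0.189). EGFR (0.84 ± 0.10) and RET (3.98 ± 0.30) rose, NTRK3 (-2.51 ± 0.08) and AXL (-0.99 ± 0.07) fell and FGFR1 (0.05 ± 0.08) did not pass. PDGFRA, at 2.17 ± 0.15 CPM with DMSO, was called lower (-0.76 ± 0.28, edgeR adjusted p = 0.039), a call lost with the replicate number as a block (0.0669; over all alternatives 0.0213 to 0.101). Cancer-testis antigens rose in 8 of 11 and fell in 1 (median 2.45, camera adjusted p = 0.0587). Tubulins and cytoskeletal genes had 4 up and 7 down of 17 (median -0.58, camera adjusted p = 0.217), and drug transporters 4 up and 5 down of 10 (median -0.14, mean 0.27, camera pointing down at adjusted p = 0.857).

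Among immune genes of H1703, the MHC class II list had a median of 4.38, or 3.71 with absent genes at their bound (camera adjusted p = 0.00013, adjusted p = 0.0939 with an estimated correlation). Checkpoint and NK ligand genes rose in 10 of 15 and fell in 1 (median 1.00, camera adjusted p = 0.018, adjusted p = 0.162 with an estimated correlation). CD274 rose from 6.47 ± 0.99 to 32.3 ± 0.90 CPM (2.33 ± 0.13). The MHC class I list divided, 7 up and 7 down of 18 (median 0.09, camera adjusted p = 0.857). The heavy chain HLA-B (2.90 ± 0.09) rose and the immunoproteasome subunit PSMB10 fell (-2.62 ± 0.23). Interferon-stimulated genes had 9 up and 17 down of 33 (median -0.86, camera adjusted p = 0.113), with BST2 (5.32 ± 0.24) and OASL (2.69 ± 0.13) up and IFITM2 down (-1.89 ± 0.10). NF-kB targets had 10 up and 11 down of 25 (median -0.21, camera adjusted p = 0.952). The chemokine CCL20 rose from 19.2 ± 0.73 to 268 ± 4.7 CPM (3.81 ± 0.08) and CCL2 fell from 212 ± 13 to 12.1 ± 0.79 CPM (-4.11 ± 0.09). Markers of other cell types rose beside the MHC class II genes. Of 7 myeloid markers 5 rose and none fell (median 2.56, camera adjusted p = 0.018, adjusted p = 0.162 with an estimated correlation). So did 2 of 2 lymphoid and 3 of 3 endothelial markers, 4 of 5 fibroblast markers (median 2.23, camera adjusted p = 0.0729) and 5 of 8 ciliated-cell markers (median 0.86, camera adjusted p = 0.277).

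In metabolism and stress, 12 of 13 mitochondrially encoded mRNAs of H1703 rose with the mitochondrial share (median 0.80, camera adjusted p = 0.0024, adjusted p = 0.596 with an estimated correlation). Nuclear oxidative phosphorylation genes had 13 up and 11 down of 31 (median -0.05, mean 0.07, camera pointing down at adjusted p = 0.952). Lysosome and autophagy genes rose in 19 of 26 and fell in 3 (median 0.86, camera adjusted p = 0.0033, adjusted p = 0.121 with an estimated correlation). Metallothioneins and antioxidant genes had 13 up and 6 down of 23 (median 0.44, camera adjusted p = 0.328). SRXN1 rose (1.99 ± 0.07) and the cystine transporter SLC7A11 fell (-2.32 ± 0.08). Of 23 pro-apoptotic genes 8 rose and 10 fell (median -0.12, mean 0.37, camera pointing up at adjusted p = 0.958). The BH3-only genes BIK (4.39 ± 0.16) and BMF (1.93 ± 0.12) rose and BOK fell (-1.15 ± 0.13). Of 10 anti-apoptotic genes 3 rose and 4 fell (median -0.19, mean 0.12, camera pointing down at adjusted p = 0.952). BIRC3 (2.95 ± 0.08) and MCL1 (0.63 ± 0.10) rose, and CFLAR (-1.34 ± 0.20) and BCL2L1 (-0.27 ± 0.08) fell. Cholesterol genes had 11 up and 5 down of 23 (11 and 6 adjusted over the list alone; median 0.20, camera adjusted p = 0.649). TM7SF2 (1.70 ± 0.09) and INSIG1 (1.23 ± 0.08) rose and CYP51A1 fell (-1.12 ± 0.09). Glycolysis had 12 up and 8 down of 21 (median 0.30, camera adjusted p = 0.660), and the ER stress response 8 up and 5 down of 18 (median 0.10, camera adjusted p = 0.730). Heat shock genes had 3 up and 10 down of 16 (median -0.46, camera adjusted p = 0.113). Ribosomal proteins had 11 up and 3 down of 30 (9 and 3 adjusted over the list alone; median 0.16, camera adjusted p = 0.590).

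The largest rises in H1703 again began at or near 0 counts. The hair keratin-associated genes KRTAP2-3 (ENSG00000212724, chromosome 17, 41059240 to 41060114) and KRTAP2-4 were at least 213-fold and at least 143-fold higher, and CYP4F2, a fatty acid hydroxylase, at least 94.0-fold. ACTBL2 (ENSG00000169067, chromosome 5, 57480016 to 57482809), an actin-like gene, went from 0.111 ± 0.10 to 317 ± 22 CPM. LAMA1, a laminin chain, was 1788 times as high (counting interval 320 to 70653), and AL078612.2, also among the largest in H1299, 1733 times (311 to 68484). Of the largest falls, SPDEF (ENSG00000124664, chromosome 6, 34537802 to 34556333), an ETS factor of secretory cells, fell by 6.38 on the log2 scale (SE 0.21). Ceruloplasmin, CP (-5.54 ± 0.14), KCTD15 (-4.97 ± 0.17) and the kinetochore gene SPC25 (-4.84 ± 0.23) fell too. NNMT, nicotinamide N-methyltransferase, went from 658 ± 52 to 18.7 ± 1.6 CPM (-5.12 ± 0.11). AC007240.1 was called too (-5.45 ± 1.71, edgeR adjusted p = 0.043), a call lost with the replicate number as a block (0.178; over all alternatives 0.0181 to 0.178).

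EdgeR called 11641 of 17273 genes in H1703, 6002 higher and 5639 lower, and 5946 of them changed 2-fold or more, 3372 up and 2574 down. Camera called 13 of 40 lists, 7 up and 6 down, 0 of them with an estimated correlation, where the lowest adjusted p was 0.0654 and 12 lists had an unadjusted p below 0.05; fry's PValue was below 0.05 for 38 lists. Library size alone, in place of TMM, lowered the median of all genes by 0.105 in this line (shift -0.105) and turned the balance to 5399 higher and 6345 lower; the changes here are relative to the TMM scaling. The call of the checkpoint list ended when the libraries of replicate 2 were left out (adjusted p = 0.0562; over all alternatives 0.0120 to 0.162). MYC, with counts of 545, 77 and 430 against 108, 1325 and 99, was not called (0.43 ± 1.36).

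**Figure D2:**
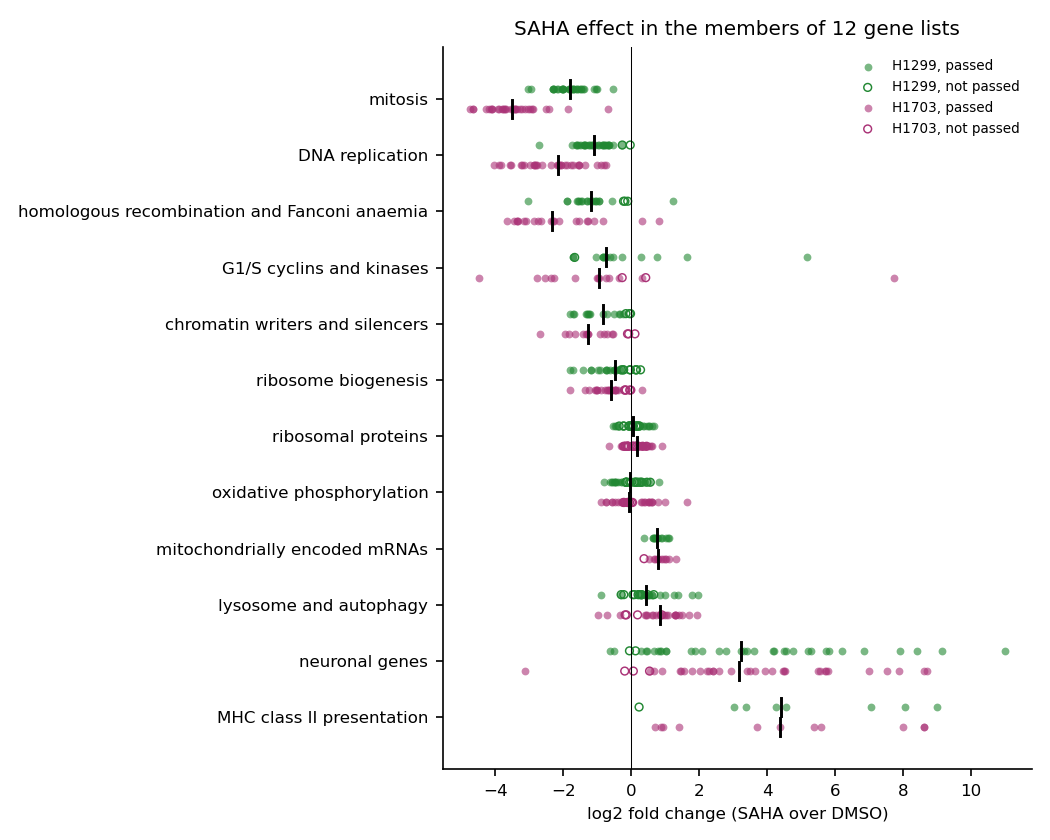
Log2 fold changes with SAHA of the tested members of 12 gene lists in H1299 and H1703; filled points passed the test, open points did not, and black ticks are list medians. Mitosis members lie below 0 in both lines, with medians of -1.79 in H1299 and -3.52 in H1703, and neuronal members lie mostly above 0.

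**Figure D3:**
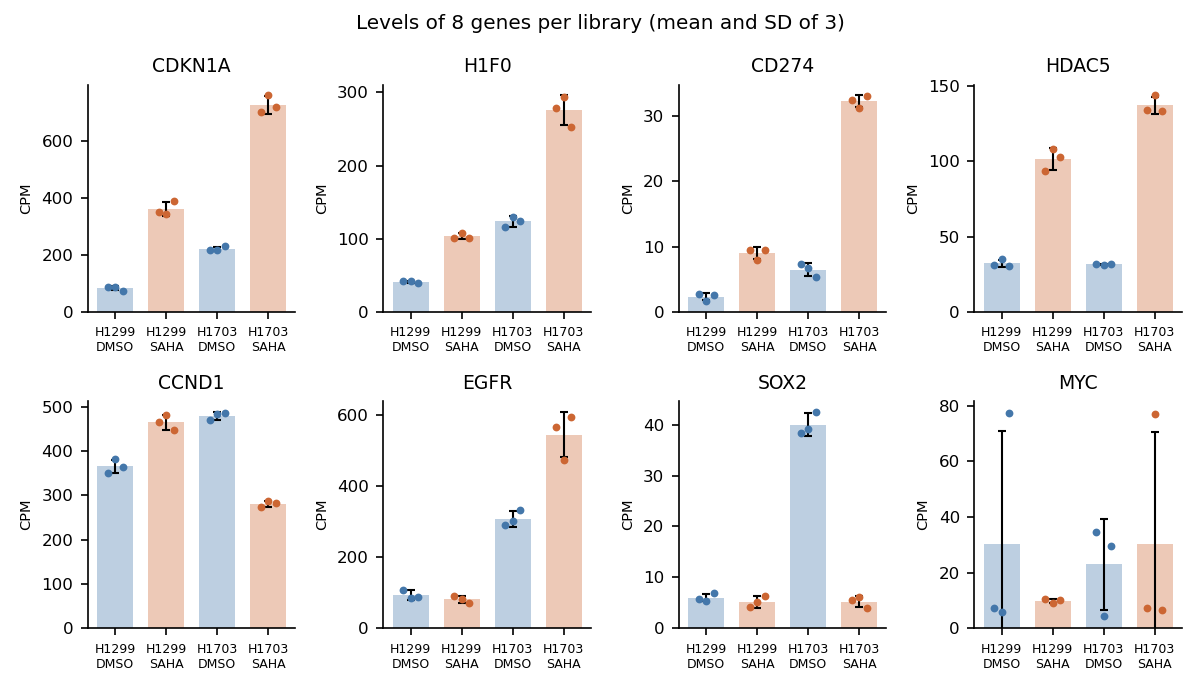
Levels of CDKN1A, H1F0, CD274, HDAC5, CCND1, EGFR, SOX2 and MYC in CPM on a linear axis; points are libraries, bars are means of 3 and whiskers are SD. CDKN1A rose from 83.5 to 362 CPM in H1299 and from 222 to 728 CPM in H1703, while single MYC libraries stand apart from the others of their group.

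The lines shared many of the large changes. Of 15654 genes tested in both, 1712 rose 2-fold or more in both lines, where independent lists of these sizes would share 489, and 1014 fell in both, against 240. Shared risers include CDKN1A, H1F0, HDAC5, CCND2, VGF, SYP, L1CAM, BST2, SRXN1 and MT1X, and shared fallers CCNA2, TOP2A, FANCD2, DNMT1 and UHRF1. In opposite directions there were 156 genes, against 693 for independent lists: 137 rose in H1299 and fell in H1703, and 19 did the reverse. All 156 passed the interaction test, but their choice by opposite calls in the same libraries nearly fixed that, so it adds no support. Across genes, log2 fold changes of the lines correlated with Pearson's r = 0.67 and Spearman's rho = 0.68, a description only, since genes are not independent replicates.

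**Figure D4:**
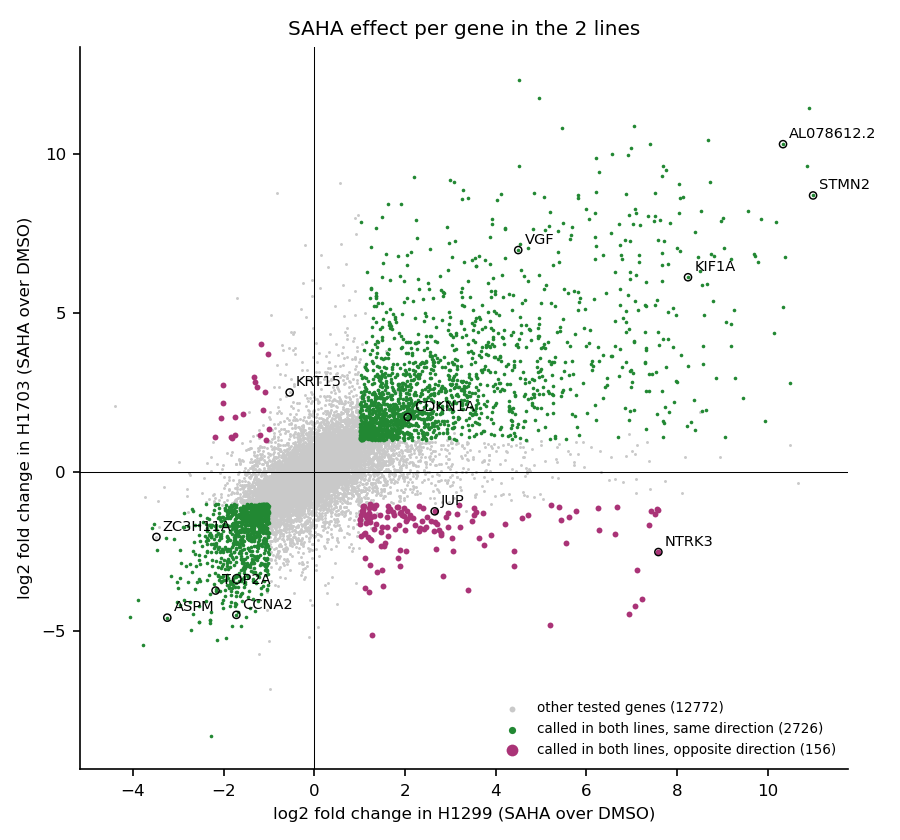
Log2 fold change with SAHA in H1299 (x axis) against H1703 (y axis) for the 15654 genes tested in both. The 2726 genes that changed 2-fold or more in the same direction are green, the 156 in opposite directions magenta and all others grey; most coloured points lie in the same-direction quadrants.

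The interaction asked where the response of H1703 differed from that of H1299. Division genes fell further in H1703: of 32 mitosis genes 28 had a lower log2 change there and none a higher one, with CCNA2 lower by -2.84 ± 0.14, KIF20A by -2.52 ± 0.16 and CCNB2 by -2.42 ± 0.15. HLA-B (2.19 ± 0.11) rose more in H1703, and so did BIRC3 (2.80 ± 0.19), an inhibitor of apoptosis that did not pass in H1299 (0.08 ± 0.16). L1CAM (-4.04 ± 0.25) rose less. Several genes turned: JUP (-3.96 ± 0.14) and CDKN1C (-3.67 ± 0.37) rose in H1299 and fell in H1703, while ABCA3 (1.58 ± 0.14) fell in H1299 and rose in H1703. CDKN1A itself differed little, with a smaller rise in H1703 by 0.40 on the log2 scale (-0.40 ± 0.12, edgeR adjusted p = 0.015).

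By list, the interaction was lower in H1703 for mitosis, in 28 of 32 genes (30 adjusted over the list alone; median -1.83, camera adjusted p = 2.4e-13, adjusted p = 0.115 with an estimated correlation). In DNA replication 27 genes were lower and 1 higher of 34 (29 and 1 adjusted over the list alone; median -1.33, camera adjusted p = 7.5e-12, adjusted p = 0.137 with an estimated correlation). Homologous recombination and Fanconi genes followed, 18 lower and 1 higher of 22 (median -1.24, camera adjusted p = 2.3e-05, adjusted p = 0.115 with an estimated correlation). So did G1/S genes, 9 lower and 1 higher of 16 (10 and 1 adjusted over the list alone; median -0.75, camera adjusted p = 0.0058, adjusted p = 0.115 with an estimated correlation). Tubulins and cytoskeletal genes were lower in 11 of 17 and higher in none (median -1.21, camera adjusted p = 2.7e-05, adjusted p = 0.194 with an estimated correlation). On the higher side stood MHC class I presentation, 8 higher and 2 lower of 18 (9 and 2 adjusted over the list alone; median 0.52, camera adjusted p = 0.015, adjusted p = 0.165 with an estimated correlation). Cancer-testis antigens were there too, 5 higher and 2 lower of 17 (median 1.89, camera adjusted p = 0.015, adjusted p = 0.265 with an estimated correlation), as were clustered histones, 7 higher and 1 lower of 17 (median 0.89, camera adjusted p = 0.048, adjusted p = 0.388 with an estimated correlation). Neuronal genes had no common direction, 15 higher and 8 lower of 38 (15 and 11 adjusted over the list alone; median -0.01, camera pointing up at adjusted p = 0.460). Of 13 mitochondrially encoded mRNAs 1 passed (0 adjusted over the list alone; median 0.01, mean -0.02, camera pointing up at adjusted p = 0.958).

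Among genes with a mean log2 CPM of 3 or more, the most extreme called interaction values belong to genes absent or nearly absent from one line with DMSO, so their size depends on the prior count and the levels say more. LBH was at 0 and 12.4 ± 1.1 CPM in H1299 without and with SAHA, against 73.8 ± 3.1 and 56.9 ± 7.0 in H1703 (interaction -11.03 ± 0.38). Of the same kind was NTRK3, at 0 and 1.46 ± 0.21 CPM against 242 ± 11 and 41.9 ± 1.3. The aldo-keto reductase AKR1B10 was at 0.117 ± 0.10 and 4.73 ± 0.52 CPM against 1249 ± 47.3 and 43.6 ± 7.1, and CPLX2 at 0 and 0.893 ± 0.91 against 157 ± 2.5 and 17.9 ± 1.2. LZTS1 was at 0 and 10.9 ± 1.8 CPM against 20.8 ± 0.90 and 36.8 ± 0.15, and the kinase gene DAPK1 at 0 and 1.25 ± 0.34 against 89.6 ± 1.2 and 28.1 ± 1.9. In the other direction, the metalloprotease MME was at 138 ± 3.4 and 81.3 ± 15 CPM in H1299 against 0 and 3.43 ± 1.4 in H1703. JPH1 was at 45.1 ± 3.3 and 40.9 ± 2.1 against 0.0213 ± 0.037 and 4.09 ± 0.76 CPM, and LINC01419 at 22.9 ± 0.88 and 44.2 ± 2.3 against 0 and 1.99 ± 0.46. KRTAP2-3, KRTAP2-4 and LAMA1 completed the 6 highest, and LAMA1 lost its call without H1299 DMSO replicate 1 (adjusted p = 0.0510; over all alternatives 9.0e-07 to 0.0510).

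EdgeR called 6672 of 19105 genes for the interaction, 2623 with a higher and 4049 with a lower log2 change in H1703, and 3593 differed 2-fold or more, 1163 and 2430. With library size alone in place of TMM the directions were 2089 and 4756, and with DESeq2's size factors 3033 and 3646. Restricted to genes expressed in both lines, a choice made after seeing the data, 1620 differed 2-fold or more, 486 and 1134. Camera called 8 of 41 lists, 3 up and 5 down, 0 of them with an estimated correlation, where 7 had an unadjusted p below 0.05 and fry's PValue was below 0.05 for 24. The clustered histone call ended with the replicate number as a block (adjusted p = 0.0869) and without replicates 2 or 3 (0.0767 and 0.0599); the MHC class I (0.0836) and cancer-testis calls (0.207) ended without replicate 2. Over all alternatives the adjusted p ran from 0.0081 to 0.388, from 0.0095 to 0.165 and from 0.0011 to 0.265.

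The last comparison set the untreated lines side by side, H1703 minus H1299 with DMSO. Epithelial transcripts stood higher in H1703. Keratin 7, KRT7, stood at 2182 ± 120.3 CPM against 6.11 ± 1.2 (8.48 ± 0.17, edgeR adjusted p = 4.9e-14). E-cadherin, CDH1, was at least 524-fold higher and the secretory gene AGR2 at least 1166-fold. Vimentin was higher in H1299 (VIM -1.70 ± 0.10, 3257 ± 373 against 1001 ± 32.6 CPM). It went against the mesenchymal list, most of whose genes stood higher in H1703, as given below. Of 25 NF-kB targets and cytokines 21 were higher in H1703 and 1 lower (median 6.13, or 5.75 with absent genes at their bound, camera adjusted p = 2.5e-07, adjusted p = 0.0710 with an estimated correlation). CD274 was higher too (1.47 ± 0.18). Cancer-testis antigens stood lower in 12 of 17 and higher in 1 (median -2.71, camera adjusted p = 1.0e-05, adjusted p = 0.0710 with an estimated correlation).

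Markers of either histology went both ways. Of 8 adenocarcinoma markers tested 5 were higher in H1703 and 3 lower (median 2.44, camera adjusted p = 0.223). MUC1 (2.43 ± 0.27) and NAPSA (2.44 ± 0.53) were higher. NKX2-1 (-3.47 ± 0.50), LAMP3 (-2.21 ± 0.19) and ABCA3 (-0.51 ± 0.10) were lower. Of 11 squamous markers 6 were higher and 2 lower (median 1.86, camera adjusted p = 0.138). SOX2 (2.73 ± 0.18), JAG1 (1.86 ± 0.10) and PERP (0.85 ± 0.07) were higher. TP63 was at least 17.6-fold higher, at 3.10 ± 0.66 CPM, TRIM29 at least 3.93-fold, and DSC3 122 times as high (counting interval 41.3 to 593). KRT15 (-3.06 ± 0.19) and S100A2 (-1.44 ± 0.23) were lower. KRT16 was near the floor in both lines, and SERPINB3 and GBP6 had 0 counts in both. TXNIP was at least 23.8-fold higher in H1703, where it reached 4.18 ± 2.0 CPM.

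Of the fixed genes, CDKN1A (1.41 ± 0.08), H1F0 (1.58 ± 0.08), HDAC6 (1.02 ± 0.10), EGFR (1.72 ± 0.12), BCL2L1 (0.85 ± 0.08) and CCND1 (0.39 ± 0.07) were higher in H1703. HDAC1 (-0.96 ± 0.07), HDAC2 (-0.96 ± 0.07) and MCL1 (-0.38 ± 0.09) were lower. HDAC3 (-0.51 ± 0.21), FGFR1 (0.10 ± 0.16) and MYC (-0.40 ± 1.29) did not pass. PDGFRA was higher in H1703 (4.67 ± 0.53) but low in both lines, at 0.078 ± 0.091 and 2.17 ± 0.15 CPM. Further lists stood higher in H1703. Epithelial genes were higher in 17 and lower in 3 of 25 (median 1.55, camera adjusted p = 0.00025, adjusted p = 0.0710 with an estimated correlation). Interferon-stimulated genes were higher in 25 and lower in 4 of 33 (26 and 4 adjusted over the list alone; median 1.13, camera adjusted p = 0.00020, adjusted p = 0.121 with an estimated correlation). For metallothioneins and antioxidant genes the counts were 17 and 3 of 23 (median 1.96, camera adjusted p = 0.00020, adjusted p = 0.121 with an estimated correlation). All 13 mitochondrially encoded mRNAs were higher (median 1.08, camera adjusted p = 0.00020, adjusted p = 0.392 with an estimated correlation). Lysosome genes were higher in 14 and lower in 2 of 26 (median 0.47, camera adjusted p = 0.033, adjusted p = 0.392 with an estimated correlation). Mesenchymal genes were higher in 14 and lower in 5 of 23 (median 1.12, camera adjusted p = 0.037, adjusted p = 0.301 with an estimated correlation). Drug transporters were higher in 7 and lower in 2 of 10 (median 2.39, camera adjusted p = 0.038, adjusted p = 0.208 with an estimated correlation), and p53 targets in 12 and 3 of 24 (median 0.58, camera adjusted p = 0.038, adjusted p = 0.301 with an estimated correlation). Mitosis genes were lower in 20 and higher in 2 of 32 (median -0.64, camera adjusted p = 0.0014, adjusted p = 0.392 with an estimated correlation). G1/S genes were lower in 10 and higher in 3 of 16 (11 and 3 adjusted over the list alone; median -0.69, camera adjusted p = 0.049, adjusted p = 0.208 with an estimated correlation).

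Between the untreated lines edgeR called 12712 of 19105 genes, 6561 higher and 6151 lower in H1703, and 7137 differed 2-fold or more, 3985 and 3152. Library size alone turned this balance, to 5457 and 7408, and to 3448 and 3931 at 2-fold. Camera called 12 of 41 lists, 9 up and 3 down, 0 of them with an estimated correlation, where 7 had an unadjusted p below 0.05 and fry's PValue was below 0.05 for 36. In no comparison did a called list's median, mean and test differ in sign. These are differences between 2 lines, and none was tested as a difference of histology.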

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

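The difference of the SAHA effect between the lines was a planned test, the interaction, while the tests of explanations and the splits of the libraries in this part were chosen only after the results were seen. Of the 142 genes that the naming rule took, 101 differed between the lines by that test, 18 of them called in opposite directions. As the median log2 difference of a list, H1703 minus H1299, division genes stood out: -1.83 for mitosis, -1.33 for DNA replication, -1.24 for homologous recombination and Fanconi genes and -0.75 for G1/S genes, with -1.21 for tubulins. Cancer-testis antigens (1.89), clustered histones (0.89) and MHC class I presentation (0.52) lay on the other side. Called up in H1299 and down in H1703 were the epithelial JUP (-3.96), the CDK inhibitor CDKN1C (-3.67), the mesenchymal TAGLN (-3.31) and TGFBI (-2.28). NNMT (-6.47), BCL2 (-1.28) and BCL2L1 (-0.69) were called the same way. PDGFRA (-4.81, its H1703 call lost with the replicate number as a block) and CCND1 (-1.12, its H1299 call lost without DMSO replicate 1) were too. So were LBH (-11.03), NTRK3 (-10.11), AKR1B10 (-10.09) and DAPK1 (-9.03). NEFH (3.97), KRT15 (2.98), ABCA3 (1.58) and MME (9.57) were called down in H1299 and up in H1703. Differences without opposite calls were CDKN1A (-0.40), HDAC6 (-0.63), HDAC3 (1.07, its call lost with no filter), EGFR (1.03), SOX2 (-2.70), VIM (0.72) and CDH1 (-5.99). The same holds for LZTS1 (-9.65), CPLX2 (-10.03), JPH1 (7.30), LAMA1 (7.31), LINC01419 (7.08), KRTAP2-3 (7.80) and KRTAP2-4 (6.79). Values beyond 5 belong to genes with few or no counts in one group (NNMT had 6, 6 and 7 in H1299 with DMSO) and are no measure of size.

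For the difference of the SAHA effect the splits of the libraries decide nothing about chance, neither for the 6672 genes nor for the 8 lists. Exchanging the treatment names of some pairs leaves part of the SAHA effect of a line in the comparison, and adds the rest to the spread between replicates, so these splits hold real effects. Exchanging 2 pairs of H1299 alone called 5061 genes and 15 lists, and exchanging all of H1703, which adds the 2 effects in place of subtracting them, called 13225 and 15. Of the 32 splits that part every replicate pair as the real one does 2 gave 6672 genes or more and 19 gave 8 lists or more. Of 25 splits drawn from all 200, pairs aside, 1, the real one, reached 6672 genes, with 5061 the highest other, and 15 gave 8 lists or more, with 15 the highest other. Within each line 3 against 3 libraries make 10 splits, too few for a share under 0.05. Every split but the real one sets 2 libraries of one group and 1 of the other against the rest. It thus keeps part of the real difference, and its lists are no chance level. In H1299 the lowest unadjusted camera p of the mitosis list in such a split was 3.9e-09. The real count and the highest other were 11016 and 1 genes and 12 and 11 lists in H1299, 11641 and 0 genes and 13 and 13 lists in H1703, and 12712 and 0 genes and 12 and 10 lists between the untreated lines. Among the 4 splits that part all pairs the highest other lists were 11, 12 and 10.

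Some counts jump between replicates of one group: 106 genes differ 5-fold or more with a highest count of 200 or more. MYC had 120, 102 and 1367 counts in H1299 with DMSO, and AHNAK 18544, 752 and 17945. One poor library is argued against, since no library set more than 45.5% of its group's jumps. For the 84 with an overlapping counted gene, reads assigned to one or the other of the overlapping genes are a candidate explanation. In 51.8% of 110 jumps the largest overlapping gene was lowest where the jumping gene was highest, against 33.3% by chance (exact binomial p = 6.8e-05). That test replaced the share with a steady sum (51.9%) after that had been seen. Its p is too small, since it takes jumps of the same gene in several groups as independent. The explanation is excluded for the 22 jumping genes without such a neighbour, MYC and PRNP among them. Of the 106 genes, 51, AHNAK included, have no steady sum with a neighbour. Their jumps stay open, and no biological explanation was tested.

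The mitochondrially encoded mRNAs rose in both lines, with medians of 0.77 and 0.80. A fall of nuclear RNA per cell would give 1 common factor. In H1299 that alone is argued against, because the 13 changes spread 2.34 times their errors, and 2.01 times at least with any 1 gene left out. The bound for this reading was set after the values were seen and is only just passed, so it marks no difference between the lines. In H1703 it stays open: the ratio was 2.01, but 1.68 without MT-ND1 and 1.93 without MT-ATP6, whose copy MTATP6P1 had 1678, 1116 and 21889 counts with SAHA. A joint rise of the respiratory chain genes of nucleus and mitochondria is argued against too: the 31 nuclear genes had medians of -0.0434 and -0.05. In H1299 a fall of nuclear RNA together with unequal mitochondrial changes stays open, as does a mitochondrial response to SAHA.

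Genes without a count in DMSO appeared after SAHA: 214 genes of H1299 and 192 of H1703 went from 0 in each DMSO library to 10 or more counts in each SAHA library, against 3 and 6 in reverse. RNA of the other line is argued against, since that line's abundant genes reached a median of 0.239% of its level at most, under a bound of 1% that replaced, after the values were seen, a rule on abundant genes at 0 counts. RNA of white blood cells is argued against in H1299, where PTPRC, TYROBP and LYZ had at most 2 counts in a SAHA library, a test first made on PTPRC alone. In H1703 it stays open: PTPRC had at most 3 counts and TYROBP at most 2, but LYZ went from 0 to 3 counts with DMSO to 20 to 44 with SAHA, and 5 of 7 myeloid and 2 of 2 lymphoid markers rose. An even background of genomic DNA reads is argued against for silent coding genes with a known length, 633 in H1299 and 383 in H1703. Counts over them varied at least 330 times as much as such a background gives. A length was known only for genes with 20 or more counts in some library, SAHA libraries included. Silent genes that stayed low are therefore missing. An earlier form, the share of the long ones still at 0 (7.07% and 18.2%), had decided nothing and is no share of all silent genes. Of all genes without a count in DMSO, 23650 of 29626 in H1299 and 24425 of 29653 in H1703 had none with SAHA. Read-through from neighbouring genes was not tested, so transcription of silent genes under SAHA stays a hypothesis.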

How the results depend on the processing

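Fits without mitochondrial genes, with protein-coding genes alone and with genes expressed in both lines were chosen after seeing the data; the other alternatives were planned. Gene counts kept within 1.5 times under scaling, filter, DESeq2, block and leave-one-out fits: leaving out 1 library gave 10346 to 10894 genes in H1299, 11004 to 11664 in H1703, 5934 to 6635 in the interaction and 12023 to 12135 at baseline. With the replicate number as a block they were 10616, 11322, 6015 and 12467 genes, with 2698 shared and 151 opposite, and 10, 13 and 7 lists. The block ended the calls of AC007240.1 in both lines, of PDGFRA in H1703, of NAPSA and NFKB1 in the interaction, of the lysosome and cancer-testis lists in H1299 and of clustered histones in the interaction, made HDAC3 pass in H1299, and changed no other call of a named gene in the comparisons recomputed for it (each named gene in the interaction), or of a list in H1299, H1703 or the interaction; lists at baseline and symbol families had no block fit. With an estimated correlation 0 lists were called in H1299, 0 in H1703 and 0 in the interaction. Interaction lists fell from 8 to 5 without replicate 2 (leave-one-out 5 to 8); the cause was not tested. Among genes expressed in both lines 1620 of 12300 differed 2-fold or more, in place of 3593 of 19105. Calls at any fold were 4777 there, in place of 6672. Why the 2-fold calls fell more was not tested. Without a fold threshold the overlap was 7030 in the same and 781 in opposite directions, as that choice widens both lists. MYC in H1299, at -1.67, ran from -2.17 to 0.50 under leave-one-out and reversed without DMSO replicate 3 (adjusted p = 0.0334, over its alternatives 0.0334 to 0.665), as that library holds the high count. Of the named-gene values under alternatives, 1147 kept direction and side of the threshold in H1299, with 8 calls gained and 10 lost. In H1703 1182 kept them and 16 lost a call, in the interaction 2867 kept them, with 12 calls gained and 38 lost, and at baseline 385 kept them and 7 gained a call. The lost calls were those of AC007240.1 (8 of 15 alternatives in H1299 and 7 of 15 in H1703, among them every left-out library except H1299 SAHA replicate 1 and H1703 DMSO replicate 3), PDGFRA in H1703 (9 of 14, among them every left-out library except SAHA replicate 1), CCND1 in H1299 without DMSO replicate 1 and BLOC1S5-TXNDC5 in one fit over 12 libraries. In the interaction they were those of NAPSA (13 of 19 alternatives, among them every left-out library except H1299 DMSO replicate 1, H1299 SAHA replicate 2 and H1703 DMSO replicate 3; adjusted p over all alternatives 0.0238 to 0.124), NFKB1 (12 of 21, among them every left-out library except H1299 SAHA replicate 1 and H1703 SAHA replicates 2 and 3; 0.0111 to 0.146) and LAMA1 without H1299 DMSO replicate 1. IFIT2 lost its call without H1299 DMSO replicate 1, H1299 SAHA replicates 2 or 3, H1703 DMSO replicate 3 or H1703 SAHA replicate 2 (over all alternatives 0.00623 to 0.0568). CCND2 lost it with DESeq2 and without H1299 DMSO replicate 3 or H1703 DMSO replicates 1 or 2 (0.0156 to 0.118), S100A2 without H1703 DMSO or SAHA replicate 2 (0.00501 to 0.0689) and HDAC3 with no filter (0.000685 to 0.0524). Calls gained there were those of CDKN2C in 4 alternatives and of AC036222.1, CCL20, CFLAR, CYP4F2, H2AFZ, SRXN1, TM7SF2 and XKR7 in 1 each. HDAC3 gained a call in 6 of 15 alternatives in H1299, without DMSO replicate 2 included, and in 5 at baseline, without H1299 or H1703 DMSO replicate 1 included. HDAC1 gained one in H1299 without SAHA replicate 3 and with protein-coding genes alone, and KRT16 at baseline with DESeq2 and without H1703 DMSO replicate 1. Of the lists, those of lysosome genes (without replicates 2 or 3) and cancer-testis antigens (without 1 or 3) lost their calls in H1299 and ciliated-cell markers gained one without replicate 3. In H1703 the checkpoint list lost its call without replicate 2 and cancer-testis antigens gained one without 1 or 3. The stricter filter ended the calls of cancer-testis antigens in H1299 and the interaction and of myeloid markers in H1703, and gave calls to ciliated-cell markers in H1299 and epithelial genes in the interaction; the cause was not tested. The balance of directions depends on the scaling. Library size alone moved the share of called genes that rose from 51.6% to 46.0% in H1703, and at baseline the share higher in H1703 from 51.6% to 42.4%, or from 55.8% to 46.7% at 2-fold. In the interaction the share with a higher change was 39.3%, against 30.5% with library size alone, 45.4% with DESeq2's size factors and 47.0% without mitochondrial genes. Small changes were often missed in the simulation, which recovered 28.4% of 1.5-fold changes in H1299 and 4.48% in the interaction. It changed far fewer genes than were called in the data, so these shares do not carry over to the real comparisons.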

Other observations

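All tests in this part were chosen only after the results were seen. Members of several symbol families changed under SAHA beside the lists above. All 12 tested HLA genes of H1299 and all 15 of H1703 rose (medians 3.20 and 3.71). In H1299 voltage-gated sodium channel genes (SCN, 9 of 10), collagens (COL, 19 of 28), ADAMTS proteases (12 of 16), WNT ligands (10 of 14), synaptotagmins (SYT, 7 of 10) and ciliary CFAP genes (16 of 23) rose. In H1703 7 of 10, 17 of 33, 9 of 14, 9 of 13, 9 of 14 and 12 of 23 rose, though camera called none of these 6 families there (adjusted p = 0.103 to 0.231) or in the interaction (0.438 to 0.999). In H1703 the clustered protocadherins PCDHB (12 of 13), integrin alpha chains (ITGA, 9 of 11) and CD-named surface genes (29 of 42) rose. In H1299 5 of 10 ITGA and 18 of 37 CD genes rose, 2 of 11 PCDHB genes rose and 1 fell (median -0.17), and the change was higher in H1703 in 11 of 14 (median difference 2.98, camera adjusted p = 5.6e-06, adjusted p = 0.0721 with an estimated correlation). Helicase subunits MCM (10 of 10 in either line), nucleoporins (NUP, 17 of 21 in either line) and splicing factors SRSF (10 and 9 of 12) fell. Of zinc finger genes (ZNF) 183 fell, 54 rose and 226 did not pass in H1299, and 164, 51 and 184 in H1703. Camera called 16, 14 and 3 families in H1299, H1703 and the interaction, 0 with an estimated correlation. With 10 splits per line, too few for a share under 0.05, the highest others were 18 and 15 families, and 2 and 3 of the splits gave as many. The other splits of a line keep part of its SAHA effect, so their families are no chance level. In the interaction 21 of 25 splits gave 3 or more and 19 was the highest other, but the split with 19 also called 5061 genes, since these splits hold part of the SAHA effect, and they decide nothing about chance.

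Zinc finger genes of chromosome 19 were often silent in H1703. Of 229 expressed in H1299, 36 (15.7%) had 3 counts or fewer over all 6 libraries of H1703. Of other genes of that chromosome it was 3 of 728 (0.412%, Fisher exact p = 2.2e-20), and of zinc finger genes elsewhere 2 of 231. In reverse it was 1 of 158. The Fisher test takes genes as independent, though some of the silent ones are neighbours, so its p is too small. Loss of 1 continuous segment of the chromosome is argued against, since 94.3% of the genes between the first and last silent one had counts in H1703. A run of 8 neighbouring silent genes (chromosome 19, 11848726 to 12137235), chosen after its values were seen, lies in an interval where 0 of 19 genes had more than 3 counts in H1703. Of 49 zinc finger genes of chromosome 19 silent in H1703 with DMSO, 0 gained 10 or more counts in each SAHA library. Of the other silent coding genes set against them 33 of 191 did (Fisher exact p = 0.00037, genes again taken as independent). Those 191 are only part of the silent coding genes of H1703. In all, 154 coding genes there went from 0 counts with DMSO to 10 or more in each SAHA library. The Fisher p holds for that part alone. The 0 of 49 gives no sign of silencing that SAHA lifts. Smaller losses, there or elsewhere, and silencing that SAHA does not lift stay open.

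The median distance between the lines did not fall under SAHA. The median absolute log2 difference between them went from 0.79 to 0.82 over 21108 genes, a difference of -0.0300 (exact permutation p = 0.61), and from 0.59 to 0.62 over the 13455 genes expressed in both, a difference of -0.0284 (p = 0.595). Both p-values come from 400 relabelings, nearly all of which mix DMSO and SAHA libraries within a line. Such relabelings hold part of the SAHA effect, so the p-values decide nothing about chance. The hypothesis that the lines move towards each other gained nothing from these distances, as neither fell. A small approach, or one of some genes, is not excluded. The second gene set was chosen by its DMSO levels, which can favour a small distance there. Another measure, not tested, went the other way. The correlation between the lines went from 0.815 with DMSO to 0.824 with SAHA over all genes, and from 0.842 to 0.870 over those expressed in both. Of the 137 genes that rose in H1299 and fell in H1703, 128 were higher in H1703 with DMSO, and of the 19 that did the reverse 15 were lower there, but these counts share the DMSO libraries with the calls and have no chance value.

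Among genes chosen after their values were seen, CDKN2A and CDKN2B had 0 counts in all 6 libraries of H1703, where their neighbour MTAP had 79 to 450. H1703 is usually described as carrying an amplified and highly expressed PDGFRA, yet PDGFRA stood at 2.17 ± 0.15 CPM in H1703 with DMSO and at 0.078 ± 0.091 in H1299. Counts alone do not settle the identity of a line, and it was not tested.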
